A study of Mus musculus with 4 samples.

How the data were processed

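Expression was measured in sorted naive CD4+ T cells of both genotypes, TACI-/- and WT, taken from spleen and lymph node tissue that was pooled. Total RNA was extracted and labelled with biotin, and each sample was hybridised to an Affymetrix Mouse Gene 2.0 ST array, per the labels' protocols. Samples were grouped by the genotype in their titles, 2 arrays per genotype. The titles call the replicates biological; whether a pool held 1 or more mice is not given in the sources used here.

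The deposited table held 1 value per probe set and array on a log2 scale. Robust multi-array average (RMA) and Partek are named in the submitters' processing notes, without versions or roles. RMA corrects the background, quantile normalizes probe intensities and summarises the probes of a set on the log2 scale; that the base is 2 was taken from RMA and from the range of the values, 0.94 to 13.2, and is not stated. No filter by the authors is recorded. All 4 columns were used. No pair of arrays shared over 0.44% identical values, so none was a duplicate.

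Of the 41345 probe sets, 23521 were paired with 1 gene symbol by the platform annotation, 1814 with several and 16010 with none there. Probe sets with several symbols were named for no gene, and those with none were used only in the closing section. A gene with several probe sets (1082 of 22180 genes) was represented by the one with the highest mean over the 4 arrays. A gene was tested where at least 2 arrays were at or above that array's 40th percentile of probe sets with 1 symbol (3.74, 3.77, 3.74 and 3.74 log2 units), which left 13782 genes. Of these, 13687 had a chromosome in a RefSeq gene table (GRCm38.p6), which was used only for names, chromosomes and the order of genes, since the array table gives no build. Members of the gene lists without a probe set of 1 symbol were not analysed here.

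Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are TACI-/- minus WT on the log2 scale, and errors are moderated standard errors (SE) or standard deviations (SD, n = 2). The prior had 4.59 degrees of freedom, and the median SE of a log2 fold change was 0.15. A looser count took an unadjusted p under 0.05 with at least a 1.5-fold change. For gene lists, 33 were fixed and the 28 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. With the correlation estimated per list, 0 of the 13 calls held; the estimate rests on 2 residual degrees of freedom. Several lists share genes (Ctla4, Irf4, the Nr4a genes), so they are not independent. The list of mitochondrially encoded genes had 0 members with a probe set of 1 symbol. The location test used the 100 tested genes on each side of Tnfrsf13b and Fisher's exact test. The NK cell, T cell receptor signalling and dendritic cell lists had medians and camera directions of opposite sign.

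Genes were named by a rule: the targeted gene, then up to 15 genes per direction past the threshold by size of change, filled to 10 with the largest changes at unadjusted p under 0.01 with separated groups (leaving out predicted genes, receptor segments and small RNAs), up to 4 members per list by p, and the sort markers. Other list members and neighbours of Tnfrsf13b named in the text were chosen after their values were seen. The lists, the rule, the tests of the comparison and the alternatives were fixed before the data were examined. The alternatives were other low-value filters, median centring, a further quantile normalization, the mean over probe sets, other variance models, the replicate number as a block, leaving out each array, other thresholds, and other set tests.

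The replicate numbers are shared between genotypes only as numbers, so the fit had no block. The fit was tested on simulated data drawn from the 13782 genes' means and the fitted variances, with 200 changed genes in each of 10 runs. It recovered 3.6% of 1.5-fold, 57.4% of 2-fold, 95.8% of 3-fold and 97.4% of 4-fold changes, with 5.78% of calls false. With cell cycle genes raised 1.5-fold, camera called that list in 10 of 10 runs and other lists in 0 of 270 tests. Genes were drawn independently in these runs, so they do not test the list calls where members of a list are correlated. A fit without one array leaves 1 sample in a genotype, which is then assumed to vary like the other genotype.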

Results

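Expression was measured in naive CD4+ T cells (sorted by surface markers that include low CD44 and no CD25) from the spleens and lymph nodes of C57BL/6 mice lacking TACI and of wild-type (WT) mice. TACI is the product of Tnfrsf13b, a receptor of the tumour necrosis factor receptor family that binds the cytokines BAFF and APRIL and is best known from B cells. Each genotype had 2 arrays, which the labels call biological replicates of pooled tissue, so 4 arrays (Affymetrix Mouse Gene 2.0 ST, 1 colour) entered the single comparison of the study, TACI-/- against WT. Each array gave 41345 values, with medians of 4.11, 4.13, 4.11 and 4.13 log2 units for TACI-/- replicates 1 and 2 and WT replicates 1 and 2. Arrays have no sequencing depth, and their number, 2 per genotype, limits the precision.

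The targeted gene showed no detectable difference between the genotypes on this array. Tnfrsf13b (1 probe set) was at 2.91 ± 0.26 log2 units (SD, n = 2) in TACI-/- cells and 2.99 ± 0.05 (SD, n = 2) in WT cells, below the low-value filter of 3.74 to 3.77 on all 4 arrays, with a log2 fold change of -0.07 ± 0.17 (SE). A probe set that is dim in both genotypes, and whose place relative to the deleted part is not given in the sources used here, does not check the genotype labels. Of the BAFF and APRIL system, Tnfrsf13c (the BAFF receptor) and Tnfsf13b (BAFF) had log2 fold changes of 0.30 and -0.13. The related receptor gene Tnfrsf12a, which the fixed list also held, had -0.29. None of these passed the threshold. None of the measured markers of the sort had an unadjusted p under 0.05. Cd4 was at 10.5 ± 0.09 in TACI-/- and 10.5 ± 0.13 in WT (SD, n = 2). Cd8a was at 3.08 and 3.01, below the filter on all 4 arrays, so its values cannot show a difference. Cd44 was at 5.91 and 5.72, and Il2ra (CD25) at 5.04 and 4.75. The log2 fold changes of Cd4, Cd8a, Cd44 and Il2ra were -0.04, 0.07, 0.19 and 0.29. Their unadjusted limma p were 0.792, 0.627, 0.232 and 0.16 in the fit without the filter.

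Which genes differ between naive T cells with and without TACI was the question of the comparison. Genes known to be induced early after lymphocyte stimulation were among those that rose in TACI-/- cells. Nr4a3 and Nr4a2, orphan nuclear receptors induced by antigen receptor signals, were 4.95-fold and 5.08-fold higher, with log2 fold changes of 2.31 ± 0.13 and 2.35 ± 0.23 (SE). Irf4, a transcription factor induced with the strength of antigen receptor signalling, was 3.05-fold higher, Ctla4, an inhibitory receptor of T cells, 2.96-fold, and Tnfaip3, which encodes the NF-kB inhibitor A20, 2.85-fold. Among 13782 tested genes, 19 passed an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 15 were higher and 4 lower in TACI-/- cells. With no filter on low values, which added tests, 3 of the 19 passed, Mid1, Nr4a3 and 2610507I01Rik; Nr4a2, Irf4, Ctla4 and Tnfaip3 then had limma adjusted p from 0.052 to 0.0565.

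The other genes that rose included signalling regulators. The dual-specificity phosphatases Dusp5 and Dusp1, which inactivate MAP kinases, were 3.69-fold and 2.58-fold higher. The kinases Sik1 and Plk2 were 3.39-fold and 2.53-fold higher, Irs2, an adaptor of the insulin receptor, 2.62-fold, and Chka, a choline kinase, 2.49-fold. Wls, which carries Wnt proteins to the cell surface, was 2.74-fold higher. Their limma adjusted p lay between 0.0246 and 0.0482. The 3 remaining genes were Apol8, an apolipoprotein L family member, which was 5.79-fold higher (log2 fold change 2.53 ± 0.21, SE), Mid1, a ubiquitin ligase, 5.33-fold (2.41 ± 0.13), and the ribosomal protein gene Rpl3, 3.17-fold (1.67 ± 0.16). Of the 15, Rpl3, Mid1 and Chka had several probe sets. The brightest of Rpl3 had a log2 fold change of 1.67 and the next 0.67, and those of Mid1 had 2.41 and 0.45. The dimmest of Rpl3 (means of 3.26 in TACI-/- and 3.55 in WT cells) and the dimmer of Chka (2.87 and 3.05) had means below the filter. Their values say nothing for or against the brighter probe sets. The 10 tested probe sets numbered next to the one used for Rpl3, a gene of chromosome 15, belong to X-linked genes, and those next to the one used for Mid1, an X-linked gene, to Y-linked genes. The next brightest of Rpl3 is numbered between probe sets of Il2rb and Tnfrsf13c, which are genes of chromosome 15. With the mean over probe sets, which takes in these dim ones, Rpl3 and Chka had log2 fold changes of 0.68 and 0.57. They did not pass there (limma adjusted p = 0.249 and 0.294).

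Of the 4 genes that fell, Apobec3, a cytidine deaminase that restricts retroviruses, was 4.08-fold lower in TACI-/- cells, at 6.51 ± 0.03 against 8.54 ± 0.32 log2 units (SD, n = 2). The transcript 2610507I01Rik was lower too, at 3.73 ± 0.03 against 5.74 ± 0.01, but below the filter on both TACI-/- arrays, so the size of its fall is not given as a fold. Its gene lies on chromosome 11, as does Tnfrsf13b, among the 100 tested genes on one side of it in the gene order of GRCm38.p6. The immunoglobulin kappa segment Igkv4-72 was 2.45-fold lower and Oas1b, of the 2'-5'-oligoadenylate synthetase family, 2.26-fold lower (limma adjusted p = 0.0404 and 0.0482). The next genes by size did not pass. Cpm, a carboxypeptidase, had a log2 fold change of -1.80 ± 0.22 (SE, limma adjusted p = 0.0735), Pnrc2 -1.07, Phf11 -0.95, Apoo -0.91 (below the filter on both TACI-/- arrays), Klrd1 -0.87 and Chil5 -0.82, with adjusted p from 0.0735 to 0.318.

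**Figure D1:**
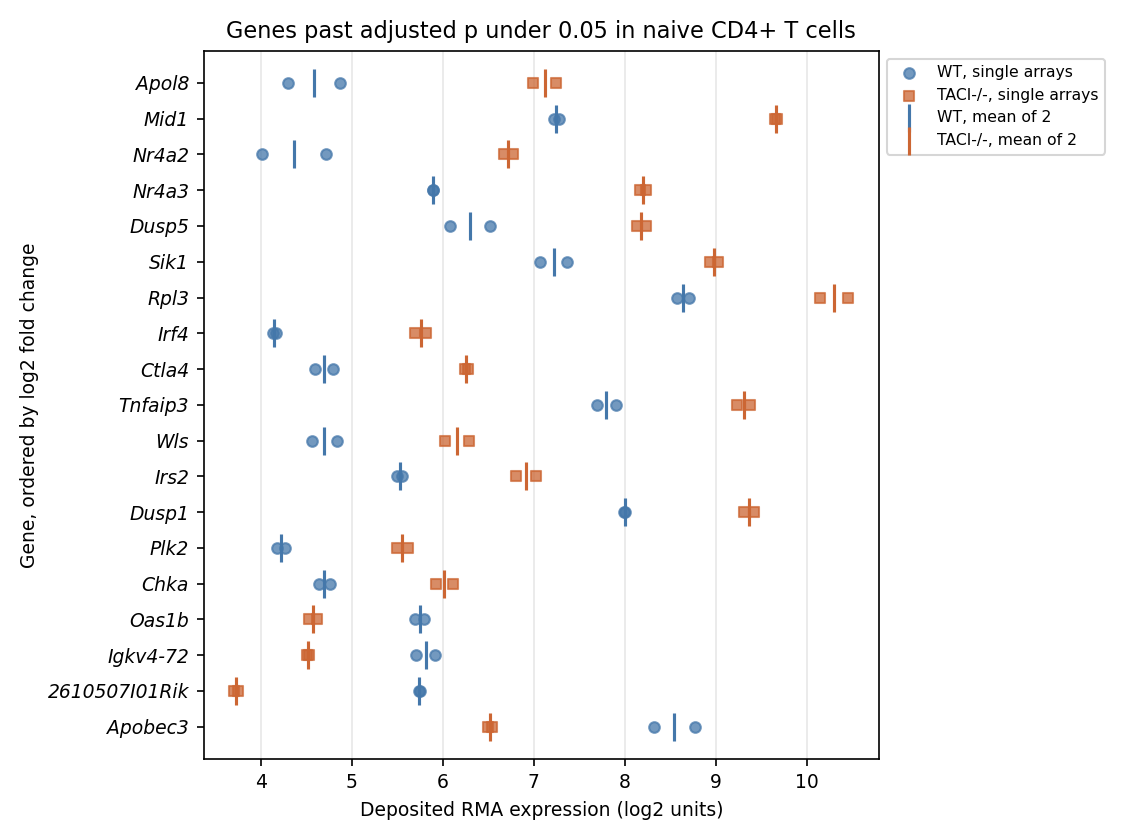
Deposited expression (x axis, log2 units) of the 19 genes past adjusted p under 0.05, on each of the 4 arrays; circles are WT, squares TACI-/- and vertical ticks the means of 2. Nr4a3 sits at a mean of 8.20 in TACI-/- and 5.89 in WT cells, and Apobec3 at 6.51 and 8.54.

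At the looser criterion of an unadjusted limma p under 0.05 and at least a 1.5-fold change, 196 genes were higher and 121 lower in TACI-/- cells, 317 in all. That count was 494 without TACI-/- replicate 1, 559 without TACI-/- replicate 2 and 582 without WT replicate 2. An unadjusted p under 0.05 was found for 8.78% of the tested genes, where chance alone gives 5%. Leaving out any 1 of the 4 arrays left no gene past adjusted p 0.05 in limma, with 1056, 1145, 721 and 1055 genes at an unadjusted p under 0.05 without TACI-/- replicates 1 and 2 and WT replicates 1 and 2. All 19 genes kept their sign in each of these fits. That outcome was fixed beforehand, since the arrays of the 2 genotypes did not overlap for any of them. With no moderation of the variance 0 genes passed after adjustment, 986 had an unadjusted p under 0.05, and these included all 19.

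The fixed list of T cell activation and memory genes was higher in TACI-/- cells as a list (camera, adjusted p = 2.2e-14; adjusted p = 0.351 with an estimated correlation). Of its 32 tested members, 4 rose over all genes tested, Nr4a3, Nr4a2, Irf4 and Ctla4, none fell and 28 did not pass; adjusted over the list alone, 11 rose. Members that did not pass over all genes included Nr4a1 at 3.04-fold, Il2rb (an interleukin receptor chain) with a log2 fold change of 1.11 ± 0.16 and the early activation marker Cd69 with 0.82 (limma adjusted p 0.1 to 0.211). The inhibitory receptor gene Tigit was at 4.60 and 3.97 in TACI-/- cells and below the filter on both WT arrays, at 3.23 and 3.14. B cell markers had a positive log2 fold change in 11 of 12 tested members, with a median of 0.32. The regulatory T cell list was also higher (camera adjusted p = 4.4e-08; adjusted p = 0.351 with an estimated correlation), with a median log2 fold change of 0.50. Of its 13 tested members 1 rose, Ctla4, which also stands in the activation list, and 6 rose when adjusted over the list alone. Ikzf2 (Helios) was at 4.33 and 4.44 in TACI-/- cells and below the filter on both WT arrays, at 3.41 and 3.49. Foxp3, a transcription factor of regulatory T cells, had a log2 fold change of 0.58 ± 0.16, while Ikzf4 had -0.04 and Izumo1r 0.03.

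Immediate early and stress genes were higher as a list (camera adjusted p = 8.9e-09; adjusted p = 0.442 with an estimated correlation). Of 28 tested members, 2 rose, Dusp5 and Dusp1, 26 did not pass, and adjusted over the list alone 8 rose. Gadd45b had a log2 fold change of 1.31, Junb 0.92, Fosb 1.05 and Fos 0.54. Among 6 heat-shock genes, Hspa8 and Hsp90aa1 had -0.13 and -0.01, while 3 were positive, and the median was 0.08. NF-kB pathway genes were higher (camera adjusted p = 0.00147; adjusted p = 0.442 with an estimated correlation), with 1 of 25 members past the threshold both over all genes and adjusted over the list alone, Tnfaip3. Nfkbid, Nfkbiz and Tnip1 had log2 fold changes of 0.95, 0.55 and 0.48. This list did not pass without WT replicate 2 (camera adjusted p = 0.0716). The 30 measured T cell receptor signalling genes did not differ as a list (camera adjusted p = 0.596, median log2 fold change 0.0024); Cd28 had 0.51 and Trat1 -0.56, and no member passed in either adjustment.

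Interferon-stimulated genes were lower in TACI-/- cells as a list (camera adjusted p = 4.7e-08; adjusted p = 0.442 with an estimated correlation). Of 29 tested members 28 had a negative log2 fold change, with a median of -0.21, yet no single member passed over all genes or adjusted over the list alone. The lowest unadjusted p belonged to Ifit2 (-0.45 ± 0.13, SE), Oas2 (-0.62 ± 0.19), Rtp4 (-0.50 ± 0.15) and Oas3 (-0.54 ± 0.17). The T cell receptor variable segments were lower (6 members, camera adjusted p = 0.00242; adjusted p = 0.442 with an estimated correlation), none passing over all genes and 3 lower when adjusted over the list alone. Trav3-4 was at 4.16 and 2.95 in TACI-/- cells and 7.56 and 6.23 in WT cells, with TACI-/- replicate 2 below the filter, and Trbv13-2 had a log2 fold change of -0.53. The 3 probe sets of Trav14d-3-dv8 disagreed, with -0.58 for the brightest, which was the one tested, and -1.09 for another; the third was below the filter on both TACI-/- arrays (3.49 and 3.66, against 7.49 and 7.38 in WT cells) and passed adjusted p 0.05 in a limma fit of all probe sets (0.023). These segments are near-identical copies that can share probes, so their separate values are uncertain.

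Among helper lineages, Th1 genes (14 members, camera adjusted p = 0.0105, and 0.0849 with no low-value filter) and Th2 genes (11 members, camera adjusted p = 0.0105) were higher as lists; both had adjusted p = 0.442 with an estimated correlation. No member of either passed over all genes. Adjusted over the list alone, 2 Th1 genes rose, Fasl (log2 fold change 0.83) and Eomes (0.79), 3 Th2 genes rose, Maf (1.01), Nfil3 (0.84) and Ccr8 (0.75), and Il13 fell by 0.62, with TACI-/- replicate 1 below the filter. The Th2 list did not pass without TACI-/- replicate 2 (camera adjusted p = 0.145) or WT replicate 2 (0.0945). Chemokine receptor and homing genes were higher (17 members, camera adjusted p = 0.0112; adjusted p = 0.442 with an estimated correlation), but not without WT replicate 2 (0.178); Cxcr4 (1.08), Ccr8 (0.75) and Cxcr5 (0.81) rose only when adjusted over the list alone. Cell cycle genes were higher (27 members, camera adjusted p = 0.0113; adjusted p = 0.56 with an estimated correlation), with a median log2 fold change of 0.15 and no member past either adjustment; the list did not pass without TACI-/- replicate 1 (0.126) or WT replicate 1 (0.0622). Stmn1 had 0.64 and Pcna 0.45. Ribosomal protein genes were lower (60 members, camera adjusted p = 0.0427; adjusted p = 0.746 with an estimated correlation), although the 1 member that passed, Rpl3, was higher; the list did not pass without TACI-/- replicate 2 (0.589) or WT replicate 2 (0.393), nor with quantile normalization again (0.363), nor with the mean over probe sets (0.14), nor with no low-value filter (0.0577).

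Lists that did not pass were the Th17 genes (camera adjusted p = 0.137), follicular helper genes (0.0873), naive and quiescent T cell genes (0.693), cytokine receptor genes (0.217), glycolysis (0.376), oxidative phosphorylation (0.0983), apoptosis and survival genes (0.986), histone genes (0.0873) and small nucleolar RNAs with microRNAs (0.596). In the naive list Il7r, the survival receptor of naive T cells, had a log2 fold change of -0.48 and Tob1, a gene of quiescence, 0.74; in the Th17 list Rora had 0.52; in the glycolysis list the glucose transporter gene Slc2a1 had 0.61. No member of these lists passed over all genes. Adjusted over the list alone, 2 follicular helper genes rose (Maf and Cxcr5), 3 apoptosis and survival genes rose (Fasl, Pim1 and Tnfrsf10b), 1 cytokine receptor gene rose (Il2rb), and no member of the other lists in this group passed.

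Markers of other cells were measured beside these groups. B cell markers were higher in TACI-/- cells as a list (12 members, camera adjusted p = 0.000161; adjusted p = 0.442 with an estimated correlation), with a median log2 fold change of 0.32. No member passed over all genes, and 2 rose when adjusted over the list alone, H2-Aa (0.57) and Ly86, which was below the filter on both WT arrays (3.22 and 3.51, against 4.33 and 3.91 in TACI-/- cells). H2-Ab1 had 0.53 and Bank1 0.44. Immunoglobulin genes were lower (12 members, camera adjusted p = 0.0311; adjusted p = 0.442 with an estimated correlation), with Igkv4-72 the member that fell in both adjustments and Ighm at 9.97 in TACI-/- and 10.3 in WT cells; the list did not pass without TACI-/- replicate 1 (0.126) or WT replicate 2 (0.583). Plasma cell markers (camera adjusted p = 0.0873, Irf4 the 1 member that rose), CD8 T cell (0.817), NK cell (0.391), dendritic cell (0.421) and monocyte, macrophage and neutrophil markers (0.693) did not pass. Adjusted over the list alone, the CD8 markers Cd8b1 (log2 fold change -0.65) and Klrd1 (-0.87) fell and Eomes rose, Klrd1 fell also in the NK list, and in the plasma cell list Irf4 alone rose. Lyz2 had a log2 fold change of -0.49 and Cd68 0.71, with no dendritic or myeloid marker past either adjustment. The erythrocyte and platelet list, the gamma delta and NKT list and the sex-linked list had 4, 3 and 3 tested members and were not tested as lists, like the BAFF and APRIL list. Their median log2 fold changes were 0.07, 0.08 and -0.17, and 1 of their members, Slamf1 of the gamma delta and NKT list, rose when adjusted over the list alone. The Y-linked genes Kdm5d, Uty and Eif2s3y lay between 6.46 and 7.59 on all 4 arrays.

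**Figure D2:**
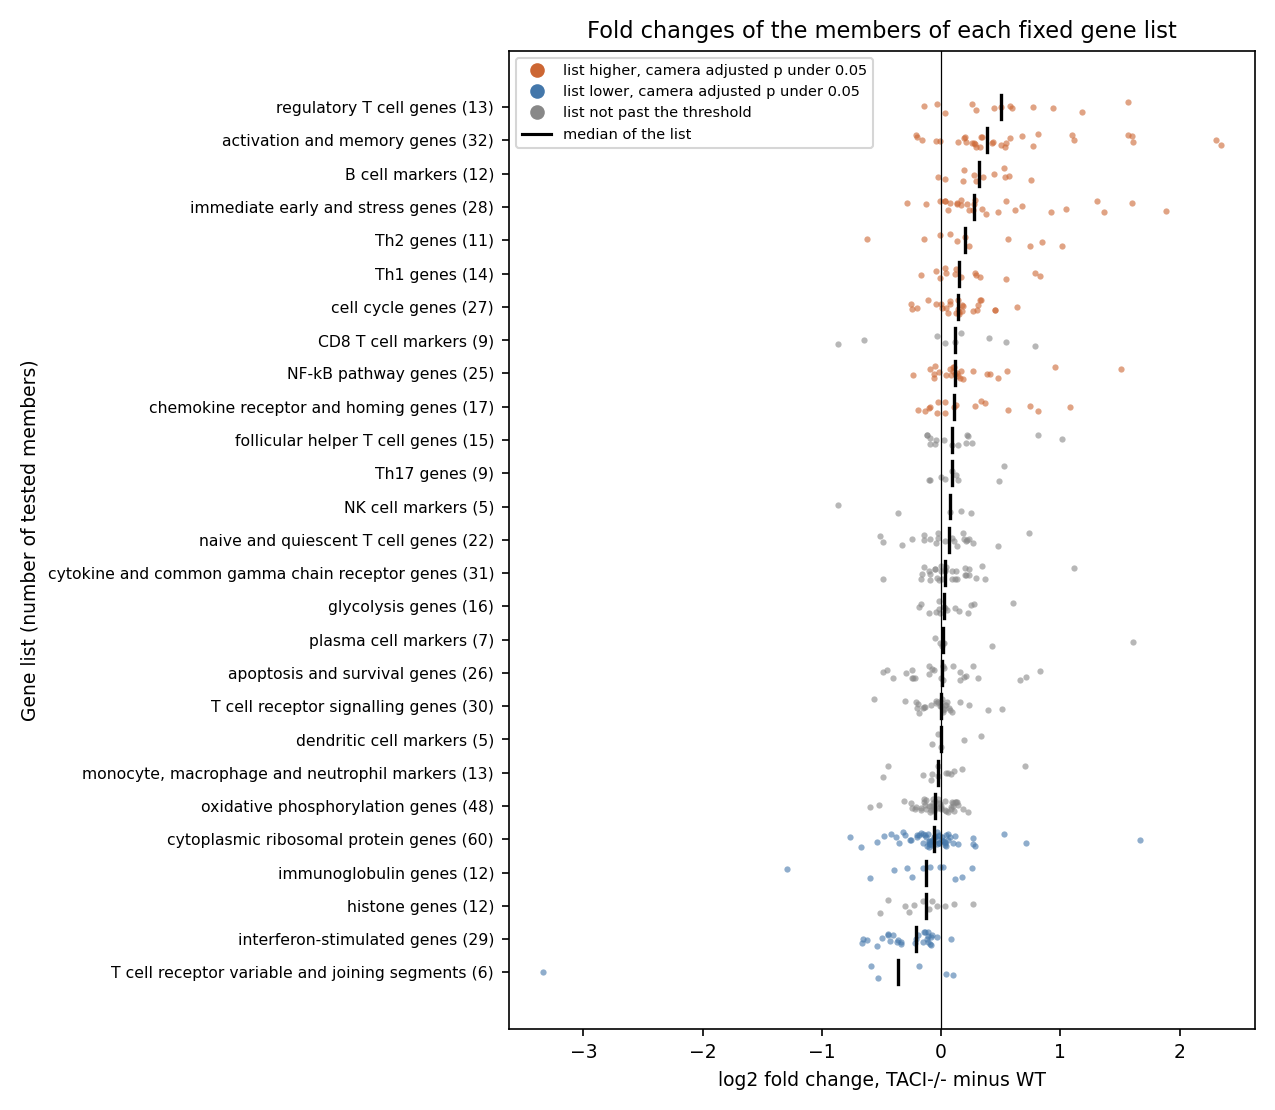
Log2 fold changes, TACI-/- minus WT (x axis), of the tested members of each fixed gene list (points) with the list's median (black bar); orange lists were higher and blue lists lower by camera with a preset correlation, grey lists did not pass, and the small RNA list is left out. The medians run from 0.50 for regulatory T cell genes to -0.36 for T cell receptor segments.

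Genes beside the targeted locus were compared with the rest, since a targeted allele can carry flanking DNA of another strain. Of the 200 tested genes nearest to Tnfrsf13b, 6 (3%) met the looser criterion, against 306 of 13487 (2.27%) elsewhere, an odds ratio of 1.33 with a 95% interval from 0.48 to 2.99 (Fisher's exact test, two-sided p = 0.468). The 6 were 2610507I01Rik, Il13, the interferon-inducible GTPase gene Irgm2 and Olfr331, which were lower in TACI-/- cells, and the clock gene Per1 and Cd68, which were higher. With the fold threshold removed, 33 of the 200 genes (16.5%) had an unadjusted limma p under 0.05, against 8.62% elsewhere (odds ratio 2.09, 95% interval 1.39 to 3.07, Fisher's exact p = 0.000343). The odds ratio was 0.43 for 50 genes on each side, where 1 of 100 genes met the criterion (95% interval 0.01 to 2.48). It was 0.85 for the whole chromosome (0.52 to 1.32) and 0.91 without variance moderation (2 of 200 genes, 0.11 to 3.39). These intervals are too wide to show a reversal.

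Over the tested genes, the arrays of one genotype correlated with each other at r = 0.982 (TACI-/-) and r = 0.984 (WT), and arrays of different genotypes at 0.976 to 0.981; genes are not independent replicates. The first principal component, with 44.9% of the variance, had TACI-/- scores of -16.7 and -10.8 and WT scores of 19.2 and 8.4. With 4 arrays there are only 3 components. The second (30.3%) set the TACI-/- arrays apart from each other, at 14.7 and -18.4, and the third (24.8%) the WT arrays, at -11.9 and 17.4.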

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

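All alternatives were planned before the data were examined. The 19 genes past adjusted p 0.05 kept their direction in all 12 alternative fits, and an unadjusted limma p under 0.05 in those of all 4 arrays. This was largely fixed by their selection on these same arrays, where their groups did not overlap. The count of genes past adjusted p 0.05 depended on the setting. It was 3 with no filter on low values (more tests), 45 with the filter at the 60th percentile (all 19 among them), 45 with a trended and robust prior (all 19 among them), 0 without variance moderation (limma; 986 genes at an unadjusted p under 0.05), 38 at an adjusted p under 0.1, and from 0 to 0 without one array (limma; 721 to 1145 genes at an unadjusted p under 0.05). It stayed within 1.5 times under median centring (19), repeated quantile normalization (15) and means over probe sets (19, of which 17 shared; Rpl3 and Chka were lost). The replicate block gave 13 genes, 12 of the 19, with 329 at the looser criterion, 13 lists and an odds ratio of 1.28 beside Tnfrsf13b; same-numbered arrays did not deviate together (r = -0.03 over genes), so the numbers are not taken as pairs. The looser count of 317 became 153 without moderation, 54 at 2-fold and 386 to 582 without one array. Of the 19 genes at an adjusted p from 0.05 to 0.1, 18 passed with the stricter filter (Ikzf2 was not tested there). With the trended prior 16 passed, and all of these passed with the stricter filter too. Among them were Cpm, Pnrc2, Rgs1, Rgs2, Cxcr4, Tgif1, Gadd45b, Dusp10, Slc16a1 and Gpbar1. None of the 19 passed in the other fits of all 4 arrays.

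The 13 list calls became 0 with an estimated correlation (2 of 28 lists at an unadjusted p under 0.05) and 0 with fry (7 of 28), and 8 to 15 without one array (8 without WT replicate 2). With an estimated correlation the adjusted p were 0.351 for activation and regulatory T cell genes, 0.442 for Th1, Th2, NF-kB, interferon, immediate early, chemokine receptor, T cell receptor segment, B cell and immunoglobulin lists, 0.56 for cell cycle and 0.746 for ribosomal protein genes. With fry, which tests a list against no change, they were 0.0679 for activation and regulatory T cell genes, 0.19 for Th2 genes and receptor segments, 0.198 for Th1 and chemokine receptor genes, 0.221 for NF-kB, 0.274 for B cell, 0.299 for interferon, immediate early and cell cycle, 0.328 for immunoglobulin and 0.704 for ribosomal protein genes. With no filter Th1 genes had 0.0849 and ribosomal protein genes 0.0577; the latter had 0.363 with repeated quantile normalization and 0.14 with means over probe sets. Without one array the adjusted p ranged from 0.00346 to 0.145 for Th2 genes, 0.000359 to 0.0716 for NF-kB pathway genes, 0.00861 to 0.126 for cell cycle genes, 0.00105 to 0.178 for chemokine receptor and homing genes, 0.00693 to 0.589 for cytoplasmic ribosomal protein genes and 0.000888 to 0.583 for immunoglobulin genes. The replicate block ended none of the 13 list calls. Outside the 13, the follicular helper list had a fry adjusted p of 0.0679 and the lowest unadjusted fry p of the 28 lists (0.00342). Arrays without background values set no bound on dim genes such as Tnfrsf13b. Camera moderates the variance itself and was not run without moderation.

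The odds ratio beside Tnfrsf13b was 0.91 without moderation, 0.85 over the whole chromosome, 0.43 for 50 genes on each side and 2.09 (past the threshold) with no fold threshold; the cause was not tested. The log2 fold change of Tnfrsf13b itself ranged from -0.25 to 0.11 (without TACI-/- replicate 1), in all cases below the filter.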

Other observations

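The tests of other splits of the arrays, of chromosome windows, of the unnamed probe sets numbered among the T cell receptor alpha segments, of the genes beside that locus, and the medians of AP-1 and heat-shock genes apart were chosen after the result was seen. Between an adjusted p of 0.05 and 0.1 lay 19 further genes, 15 higher and 4 lower in TACI-/- cells. Those higher included Rgs1 and Rgs2, regulators of G protein signalling, with log2 fold changes of 1.19 ± 0.15 and 1.25 ± 0.17 (SE), the chemokine receptor gene Cxcr4 (1.08), the transcriptional repressor gene Tgif1 (1.22), the MAP kinase phosphatase gene Dusp10 (1.06), Slc16a1, a lactate transporter gene (0.95), and Gpbar1, a bile acid receptor gene (1.09). They are named after their values were seen, and limma adjusted p lay between 0.0735 and 0.0929. With the mean over probe sets, Rgs2 had a limma adjusted p of 0.317.

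Some genes of early activation were higher in TACI-/- cells, 4 of 32 members of the activation list and 2 of 28 of the immediate early list (adjusted p = 0.351 and 0.442 for the lists with an estimated correlation), which may come from handling, from other cells in the sort or from chance. Stress during dissociation and sorting was expected to raise AP-1 and heat-shock genes together. Their median log2 fold change was 0.17 ± 0.12 (bootstrap SE, 11 genes). This met the bound set in advance against such stress, a median under 0.2 staying under 0.5 with 1 SE added. A sign-flip bound had been planned, and a bootstrap over genes was used instead. That SE does not measure the spread between arrays, and the median is the value of Hspa1b, whose own SE was 0.53. A response of both together is therefore not decided. The 5 AP-1 genes had a median of 0.54 ± 0.28 and the 6 heat-shock genes 0.08 ± 0.12, a difference that was not tested, and AP-1 genes belong to the pattern itself, so handling that raises them alone is not decided. More regulatory or memory T cells in the sort would raise their markers, but the median of 15 was 0.26 ± 0.09, between the bounds set in advance. Foxp3 was at 0.58, Ikzf2 below the filter in WT cells only, and Capg, S100a10 and Lgals1 at -0.15, -0.16 and -0.21. The gates on CD25 and CD44 are meant to remove many such cells, but no measure of the purity of the sort was used here. B cells stay open too, with a median of 0.32 over 12 markers (H2-Aa 0.57, Cd79a 0.29), though a CD4 sort is meant to remove them. Beside these, the brightest probe set of Ighm had -0.28 and the next brightest -0.01. The 4 arrays have 3 splits of 2 against 2, too few for a share under 0.05; the real split, the 1 with as many genes, gave 19 and the highest other 0, and the loss of TACI itself stays open as untested.

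Some changed genes lay near each other on chromosomes. For those near Tnfrsf13b, on chromosome 11, flanking DNA of another mouse strain is a candidate explanation. Apol8 and Apobec3 lie within 49 of the 560 tested genes of chromosome 15, and 2610507I01Rik lies near Tnfrsf13b. Rpl3 lies near Apobec3, but its brightest probe set is numbered among X-linked genes, as the one used for Mid1 is among Y-linked ones. The next brightest of Rpl3, numbered among genes of chromosome 15, was higher too (8.77 against 8.11, log2 fold change 0.67 ± 0.14, SE). Rpl3 is thus left out of a window below for the numbering of its brightest probe set alone. The fullest window of 20 neighbouring genes held 4 genes at the looser criterion, and as many came up in shuffles with p = 0.90 (permutation test, 10000 shuffles), which a random scatter would give; for the 19 genes past adjusted p 0.05 the fullest window of 100 held 3 (permutation p = 0.117), and without Rpl3 and Mid1 2 (p = 0.857). Beside Tnfrsf13b the odds ratio was 1.33 with an interval up to 2.99. It was 0.43 with 50 genes on each side, 0.85 over the whole chromosome and 2.09 with no fold threshold. Flanking strain DNA therefore stays open for the genes of chromosome 11. The test beside Tnfrsf13b does not bear on the genes of chromosome 15, Apobec3 among them. DNA of another strain was not tested there and stays open too. That neighbours shared a change of expression was not tested.

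In the fit of all 41345 probe sets, 5 passed adjusted p 0.05 (limma), 1 a dimmer probe set of Trav14d-3-dv8 (3.49 and 3.66 in TACI-/- and 7.49 and 7.38 in WT cells) and 4 without a gene name here, all 5 lower in TACI-/- cells and numbered between the first and last named T cell receptor alpha V segment. Probe set 17300177 was at 3.50 and 3.09 in TACI-/- and 10.2 and 9.71 in WT cells, and 17300183 at 3.97 and 3.49 against 9.50 and 9.50; values at or below the filter give no exact fold. In that run of numbers 44 of 125 unnamed probe sets above the filter met the looser criterion, 37 lower and 7 higher, against 861 of 8948 elsewhere (odds ratio 5.1, Fisher's exact p = 1.5e-14, with near-identical copies not independent). A candidate explanation is another haplotype of the alpha locus in one genotype: of the 40 tested genes beside it 1 met the criterion, Dad1 (odds ratio 1.1, 95% interval 0.03 to 6.56), which leaves it open, and an earlier test on the 5 probe sets that fell below the filter in TACI-/- cells was set aside because the pattern itself fixed its outcome. Other use of V segments was sought in the beta locus, where 0 of 19 probe sets around Trbv13-2 changed 2-fold (Fisher's exact p = 1); this met the bound set in advance against it, but that bound was too weak, since 0 of 19 allows up to 17.6% where 3.94% changed elsewhere and alpha use can shift without beta, so the reading was changed after the value was seen and this too stays open.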
